A study of Mus musculus with 2 samples.

How the data were processed

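RNA sequencing was done on 2 libraries of mouse primary chondrocytes grown ex vivo as micromass cultures, in which cells are plated at high density as a drop so that they form cartilage-like nodules. Per the labels, 1 culture received an adenovirus carrying Cre recombinase, an enzyme that excises DNA flanked by loxP sites, and carries the label of an Hdac3 knockout. The other received a control adenovirus carrying green fluorescent protein (GFP) and carries the label of wild type. The strain is given as C57Bl/6. Total RNA was extracted with TRIzol and libraries were made with the Illumina TruSeq v2 mRNA kit, per the labels' protocols. Each group holds 1 sample, and the labels do not say how many animals or dishes were combined in it.

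The submitters' processing notes name bcl2fastq 1.8.4, TopHat2 2.0.6, HTSeq (without a version) and the mouse build mm10. The strand setting of the counting, the annotation and the treatment of reads with several alignments are not given in the sources used here. One deposited table was used. The authors deposited log2 values of normalized gene counts, with 1 column per library, for 13138 genes, together with their mean and their difference. The transform is not described. The difference column is headed rLogFC, and a regularized log, which shrinks the differences of genes with few reads, is inferred here from that heading and from the values: the standard deviation (SD) of the difference over genes was 0.15 for genes with a mean log2 value from 5.64 to 7 and 0.23 for those from 9 to 11, whereas counting noise alone would make it wider at low counts. If they are such values, differences of less abundant genes are understated. Folds given here are folds of the transformed values. The lowest mean log2 value in the table was 5.00, so less abundant genes were not analysed here. The deposited difference equals GFP minus Cre in every row, so a negative deposited value is higher in Cre. All differences given here are Cre minus GFP.

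The deposited values hold no read counts, so the depth of each library is unknown and no counting interval or limit of detection can be given. They hold no replicate and no p-value either. With 1 library per group, no test across libraries was possible, and every difference compares these 2 libraries and not the conditions. The plan made before the data were examined had foreseen ratios with a pseudocount, which the log scale made needless, and counts of the authors' adjusted p-values, which the table used here does not hold.

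Genes with a mean of at least 50 on the count scale (5.64 on the log2 scale) were compared, which kept 12809 genes. Genes were counted as higher or lower by size alone, at 2-fold or more. To give a scale for single genes, 90% of these genes differed by less than 0.33 and 99% by less than 0.92 on the log2 scale. The spread was wider among the 520 genes with a mean log2 value of 13 or more (SD 0.49). Their 5th and 95th percentiles were -0.52 and 0.58, so the scale is too narrow for the most abundant genes. Chosen before the data were examined were 32 gene lists, the minimum, the fold threshold, the rule for named genes and the alternatives. They were drawn from general knowledge of cartilage, of Hdac3 and of published work on this model, which names cytokines and matrix metalloproteinases. The direction of the lists of inflammatory genes and matrix proteases is therefore not independent evidence. Other lists came from the same knowledge, so their direction may not be independent evidence either. For each list, the median difference of its measured members was set against the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. Percentiles among random lists describe these 2 libraries. Genes of 1 list often vary together between any pair of cultures, so random lists of unrelated genes are a narrow scale. Of the 31 lists with a measured gene, 11 lay above and 10 below the middle 95% of random lists, where 1.55 would be so by chance among unrelated genes. Some genes belong to more than 1 list, so these are not separate results. Runx2 and Sp7 are in the hypertrophy and osteoblast lists, and Pgk1 and Gapdh in the glycolysis and common reference lists. The mitochondrially encoded genes had no member in the table.

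Genes were named by these rules: Hdac3, the 10 highest and 10 lowest differences with an established symbol, up to 4 members of each list with the largest absolute difference, and some members fixed by name. Genes named outside these rules are said to have been chosen after their values were seen. Gene identifiers in the table join chromosome and symbol. A symbol that contains a full stop is cut there, and 6 rows share the symbol Epb4 on different chromosomes, so these were kept in the counts of genes and left out of the lists. Coordinates come from GENCODE release M21 on GRCm38, the assembly also called mm10, matched by symbol and chromosome, which 11906 of 13138 genes (90.6%) allowed. Where only an older symbol matched, NCBI's gene table for the same assembly was used. Reads of near-identical gene copies cannot be told apart in gene totals: Gapdh, which has many pseudogenes, had a mean log2 value of 10.78, against 15.41 for the glycolytic gene Pgk1.

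Computation used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots used matplotlib 3.10.9. The steps were tested on simulated data made from the 12809 real gene means, with differences of 0.3 or more set to 0 and the rest shuffled among genes of like abundance. This leaves less spread than the real data have and makes recovery easy, so the test checks the computation and not the sensitivity. For the comparison of Cre with GFP, 100% of 200 genes planted with a log2 shift of 1.5 were recovered with 0 others. Of 100 lists of 25 genes shifted by 0.3, each set against 1000 random lists, 100 lay above the 97.5th percentile, and 3 of 100 unshifted lists lay outside the middle 95%. Alternatives were no minimum, a minimum 10 times higher or 0.2 times as high, thresholds of 1.5-fold and 4-fold, median scaling, scaling to equal totals with or without Rn45s and Lars2, the mean of a list in place of its median, and random lists without matching.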

Results

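The data set compared gene expression in 2 cultures of mouse chondrocytes, 1 transduced with Cre adenovirus and labelled Hdac3 knockout, and 1 transduced with GFP control adenovirus and labelled wild type. The question stated for the series was which genes are higher and lower in chondrocytes that lack Hdac3, a histone deacetylase that works in nuclear receptor corepressor complexes, so that histone H3 lysine 27 acetylation could be examined at those genes. The acetylation data were not analysed here. Each group had 1 library, so no difference has a replicate check and no p-value is given. The values are the authors' deposited log2 normalized counts, and the depth of each library is unknown. Precursor ribosomal RNA (Rn45s) held 22.9% of the summed linear values in the library labelled Cre and 22.8% in the library labelled GFP.

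Hdac3 itself did not differ between the libraries. Its log2 normalized count was 10.68 in the library labelled Cre and 10.69 in the library labelled GFP, a difference of -0.0043 whose sign turned under scaling to equal totals (0.0033). It is a protein-coding gene on the minus strand of chromosome 18, at 37935844 to 37955016 (GRCm38). Hdac3 was chosen before the data were examined as a check of the labels, and its level total gave no sign of a knockout. The value is a total over the whole gene, and the sources used here do not say which exons Cre removes. Transcripts that lack those exons would still be counted through the rest, so a level total does not exclude such a loss either. The check therefore did not bear out the labels, and the libraries are called by their labels throughout. Other histone deacetylases and sirtuins were also level, with a median difference of 0.03 over 15 genes and a range from -0.31 for Hdac11 to 0.13 for Hdac6. Hdac1 differed by 0.04 and Hdac2 by -0.10. Among 8 corepressor complex genes the median was 0.01, and Ncor1, which encodes the corepressor scaffold that binds Hdac3, had a log2 value of 12.64 on average in both libraries. Neither list left the middle 95% of matched random lists.

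Among 12809 genes, 94 were at least 2-fold higher and 9 at least 2-fold lower in the library labelled Cre. The highest was Saa3, an acute-phase gene of the serum amyloid A family of similar copies (chromosome 7, 46711998 to 46715700), with 16.36 in the library labelled Cre against 12.96 in the library labelled GFP, a 10.5-fold difference. It was followed by Mmp3, the matrix-degrading enzyme stromelysin (chromosome 9, 7445822 to 7455975), at 9.63-fold, by the chitinase-like cartilage glycoprotein gene Chi3l1 at 9.45-fold, and by Lcn2, an iron-sequestering lipocalin, at 8.68-fold. The neutrophil-attracting chemokines Cxcl1 and Cxcl5 were 7.62-fold and 7.17-fold higher. Aspm, a mitotic spindle gene on chromosome 1 (139454772 to 139494091), was 6.06-fold higher. Steap4, a metalloreductase, was 5.38-fold higher, Lbp, which binds bacterial lipopolysaccharide, 5.13-fold, and the pantetheinase gene Vnn1 5.09-fold. The difference was 4-fold or more for 15 higher genes and 1 lower gene.

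The lower genes differed less. Tmem158, a membrane protein gene on chromosome 9 (123259053 to 123260764), was 4.13-fold higher in the library labelled GFP. Akt1s1, which encodes an AKT substrate within the mTOR complex and overlaps Tbc1d17 and Mir707, was 3.61-fold higher there, and C1qtnf3, a secreted cartilage protein gene, 2.78-fold. Egln1, which encodes an oxygen-sensing prolyl hydroxylase, was 2.25-fold higher in the library labelled GFP, and Smpd3, a neutral sphingomyelinase gene needed for skeletal mineralization, 2.22-fold. The extracellular matrix gene Ogn was 2.11-fold, Fam180a 2.11-fold, the BMP antagonist gene Chrdl1 2.01-fold and the microfibril gene Mfap4 2.01-fold higher there. Omd, a proteoglycan gene next to Ogn, lay just short of the threshold, at 11.94 against 12.93.

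**Figure D1:**
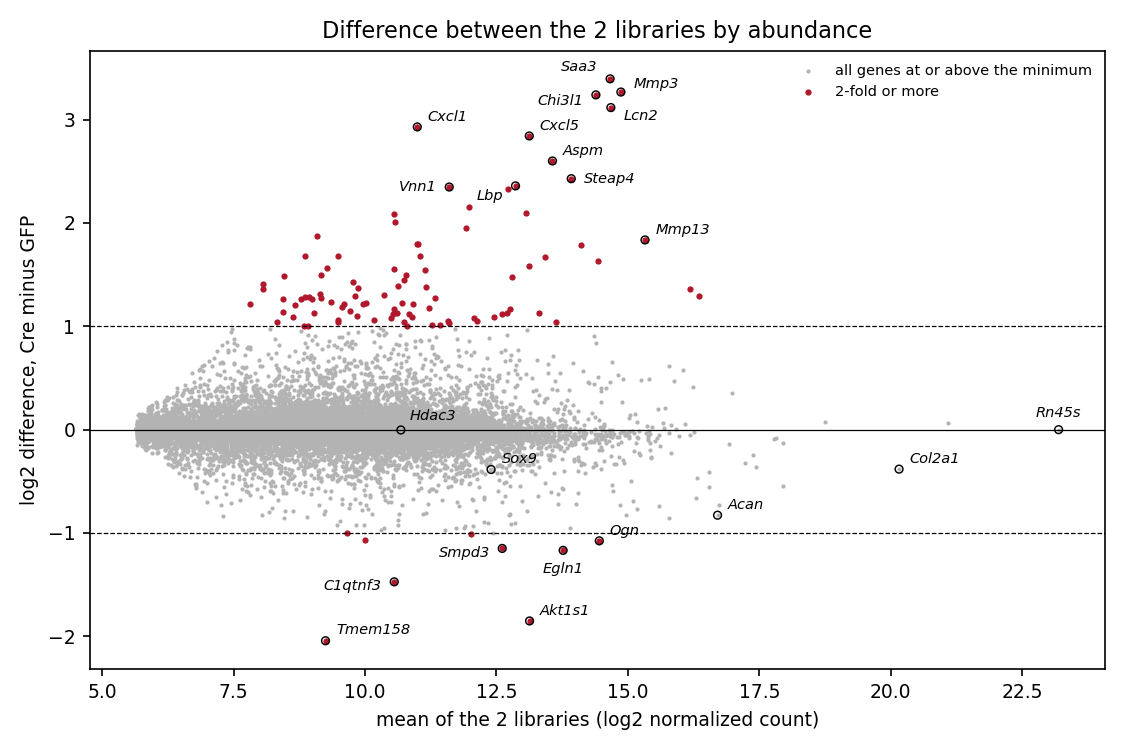
Each point is 1 of 12809 genes. The x axis is the mean log2 normalized count of the 2 libraries and the y axis the log2 difference, Cre minus GFP. Dashed lines mark 2-fold, red points lie at or beyond them, and open circles mark named genes. The 94 red points above outnumber the 9 below, and Hdac3 lies at 0.

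Inflammatory and acute-phase genes were higher as a group in the library labelled Cre. Of 24 measured members, 23 lay above 0, 16 were at least 2-fold higher and 0 were 2-fold lower, with a median of 1.30 and quartiles of 0.66 and 1.79. None of 10000 matched random lists had so high a median. Saa3, Lcn2, Cxcl1 and Cxcl5 led the list, and Csf1, named after its value was seen, was its only member below 0, at -0.16. The list was drawn with knowledge of published work on this model, so its direction is not independent evidence. Il6 was not in the table and was not analysed here. Interferon-stimulated genes were higher by less: 33 of 35 lay above 0, 2 were 2-fold higher and 16 were 1.5-fold higher, with a median of 0.50. The chemokine gene Cxcl10 was 2.82-fold higher, the guanylate-binding protein gene Gbp2 2.58-fold, and Isg15 and Ifit1 each differed by 0.85. In the list of JAK-STAT and cytokine receptor genes, 18 of 21 lay above 0, with a median of 0.33. Its leading members were the NF-kappaB cofactor gene Bcl3 at 2.44-fold, the TNF receptor gene Tnfrsf1b at 2.18-fold, the feedback inhibitor gene Socs3 at 2.15-fold and the oncostatin M receptor gene Osmr at 1.64-fold. No random list reached the medians of these lists.

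Markers of macrophages and osteoclasts lay on both sides of 0. Their median difference was 0.23 over 20 genes, above all random lists, with quartiles of -0.06 and 0.64. The macrophage surface gene Emr1 was 2.11-fold higher in the library labelled Cre, the monocyte receptor gene Cd14 and the osteoclast phosphatase gene Acp5 each 2.06-fold and the lysozyme gene Lyz1 1.88-fold. The macrophage mannose receptor gene Mrc1, named after its value was seen, differed by -0.73. Skeletal muscle markers had a median of 0.15 over 13 genes, led by Ttn at 0.67, at percentile 99.9 of random lists. Endothelial markers (median 0.07 over 8 genes), fibroblast and perichondrial markers (-0.03 over 19) and neuronal and glial markers (-0.10 over 6) stayed within the range of random lists, as did the 1 measured erythroid gene, Alas2, at 0.03. The neuronal and glial list left that range by its mean (percentile 0.83) and at a minimum 10 times higher (percentile 0.12), which kept 2 genes.

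Matrix proteases were higher as a group, most of them by little and a few by far more. Of 26 measured genes, 20 lay above 0 and 3 were at least 2-fold higher, with a median of 0.14, above all 10000 random lists. Mmp3 was 9.63-fold higher, the collagenase gene Mmp13 3.57-fold, the gelatinase gene Mmp9 2.33-fold and the aggrecanase gene Adamts5 1.58-fold. This list too was drawn with knowledge of published work. Protease inhibitors split, with 5 of 10 above 0 and a median of 0.06 inside the range of random lists. Serpina3n was 3.47-fold and the metalloproteinase inhibitor gene Timp1 1.95-fold higher in the library labelled Cre. Serpina3g differed by 0.85, and both Serpina3 genes belong to a family of similar copies that can share reads, while Timp3 was 1.81-fold higher in the library labelled GFP.

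Genes of the cartilage matrix were lower as a group in the library labelled Cre, none of them by 2-fold. Of 24 measured members, 21 lay below 0 and 8 were at least 1.5-fold lower, with a median of -0.53 and quartiles of -0.67 and -0.31. All 10000 matched random lists had a higher median. Matn3, which encodes matrilin 3, differed by -0.89, the aggrecan core protein gene Acan by -0.83, the link protein gene Hapln1 by -0.77 and Susd5 by -0.72. Col2a1, the main cartilage collagen, had 19.97 in the library labelled Cre against 20.35 in the library labelled GFP, a difference of -0.38. The highest member was Prg4, which encodes the lubricant of joint surfaces, at 0.47, and the abundant matrix gene Comp lay at -0.04, both named after their values were seen. Chondrocyte transcription factors and regulators had a median of -0.20 over 16 genes, with 12 below 0, and all random lists lay higher. The growth factor receptor gene Fgfr3 differed by -0.91, and the transcription factor genes Sox9 and Sox6 by -0.39 and -0.34, while Pax9 differed by 0.39.

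Genes of chondrocyte hypertrophy, the enlargement that precedes mineralization, split in direction. Their median was -0.19 over 19 genes, below all random lists, while their mean was 0.0072, at percentile 47.2. Mmp13 was 3.57-fold, the matrix phosphoprotein gene Spp1 2.56-fold and Vegfa 1.59-fold higher in the library labelled Cre. Col10a1, the collagen of hypertrophic cartilage, was 1.83-fold higher in the library labelled GFP, and Runx2 differed by -0.23. Ihh was not in the table and was not analysed here. All 11 measured osteoblast genes lay below 0, with a median of -0.23 (percentile 0.02) and 0 of them at 1.5-fold. The largest difference there was -0.47, for Sp7, a transcription factor gene of bone formation that is also in the hypertrophy list.

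The signalling lists differed in direction. Several hold both activators and inhibitors of a pathway, so their medians do not give the direction of signalling. In the hedgehog and Wnt list, 21 of 26 members lay below 0, with a median of -0.21, below all random lists. The Wnt modulators Sfrp2, Nkd1 and Frzb differed by -0.91, -0.86 and -0.83, and the Wnt receptor gene Fzd9 by -0.68. In the TGF-beta, BMP and activin list, 20 of 29 lay below 0, with a median of -0.19, likewise below all random lists. Chrdl1 differed by -1.01 and Gdf10 by -0.64, while the extracellular matrix gene Ltbp2 and the activin subunit gene Inhba differed by 0.92 and 0.62. ERK feedback and immediate early genes had a median of 0.16 over 26 genes, with 22 above 0, above all random lists. The stress-induced gene Ier3 was 2.95-fold higher in the library labelled Cre, Junb and Phlda1 were each 1.64-fold higher, and the ERK phosphatase gene Dusp6 differed by 0.34. For AKT phosphatases and mTOR regulators the median was 0.04 over 13 genes, inside the range of random lists. Ddit4 differed by 0.80 and the AKT phosphatase gene Phlpp1 by -0.02.

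Glycolysis and hypoxia genes were higher as a group in the library labelled Cre. All 23 measured members lay above 0, 8 by at least 1.5-fold and 2 by at least 2-fold, with a median of 0.51 that no random list reached. The oxygen sensor gene Egln3 was 2.28-fold higher, the carbonic anhydrase gene Car9 2.27-fold, the vasodilator peptide gene Adm 1.93-fold and the collagen hydroxylase gene P4ha2 1.63-fold. Egln1, which is not a member of this list, was lower, as given above, and its relation to these genes was not tested. Proliferation genes were close to level, with a median of 0.07 over 35 genes, a highest member of 0.31 (Ccne1) and Mki67 at 0.03. The median of the proliferation list lay at percentile 99.3 of random lists. The p53 targets also had a median of 0.07, over 24 genes, at percentile 98.6, with Cdkn1a at 0.13 and the death receptor gene Fas at 0.86. By their means, the proliferation and p53 lists lay at percentiles 91.3 and 91.8, inside the middle 95%.

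Lipid and stress lists differed by little. Unfolded protein and integrated stress response genes had a median of -0.15 over 21 genes (percentile 0.01), with 18 below 0, and Chac1 differed by -0.56. Cholesterol synthesis genes had a median of -0.10 over 18 genes and lipid storage genes -0.09 over 25, at percentiles 0.35 and 0.58, although Cebpd was 2.73-fold and Cebpb 1.89-fold higher in the library labelled Cre. Both encode C/EBP transcription factors of adipocyte and inflammatory genes. Neither list stayed outside the middle 95% by its mean: cholesterol synthesis lay at percentile 3.47, and lipid storage turned to 0.049, at percentile 76.0, and lay at percentile 11.5 with a minimum 10 times higher. Limb and axial patterning genes had a median of -0.16 over 16 genes, also at percentile 0.01. Ribosomal protein genes had a median of -0.05 over 32 genes, within the range of random lists. Common reference genes had a median of 0.07 over 14 genes, at percentile 98.8 (88.5 by the mean, 95.3 without matching), with Pgk1 at 0.49, Gapdh at 0.45 and Actb at -0.07. The 5 measured sex-linked genes were present in both libraries and close to level, with Xist at -0.06 and Ddx3y at -0.03.

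**Figure D2:**
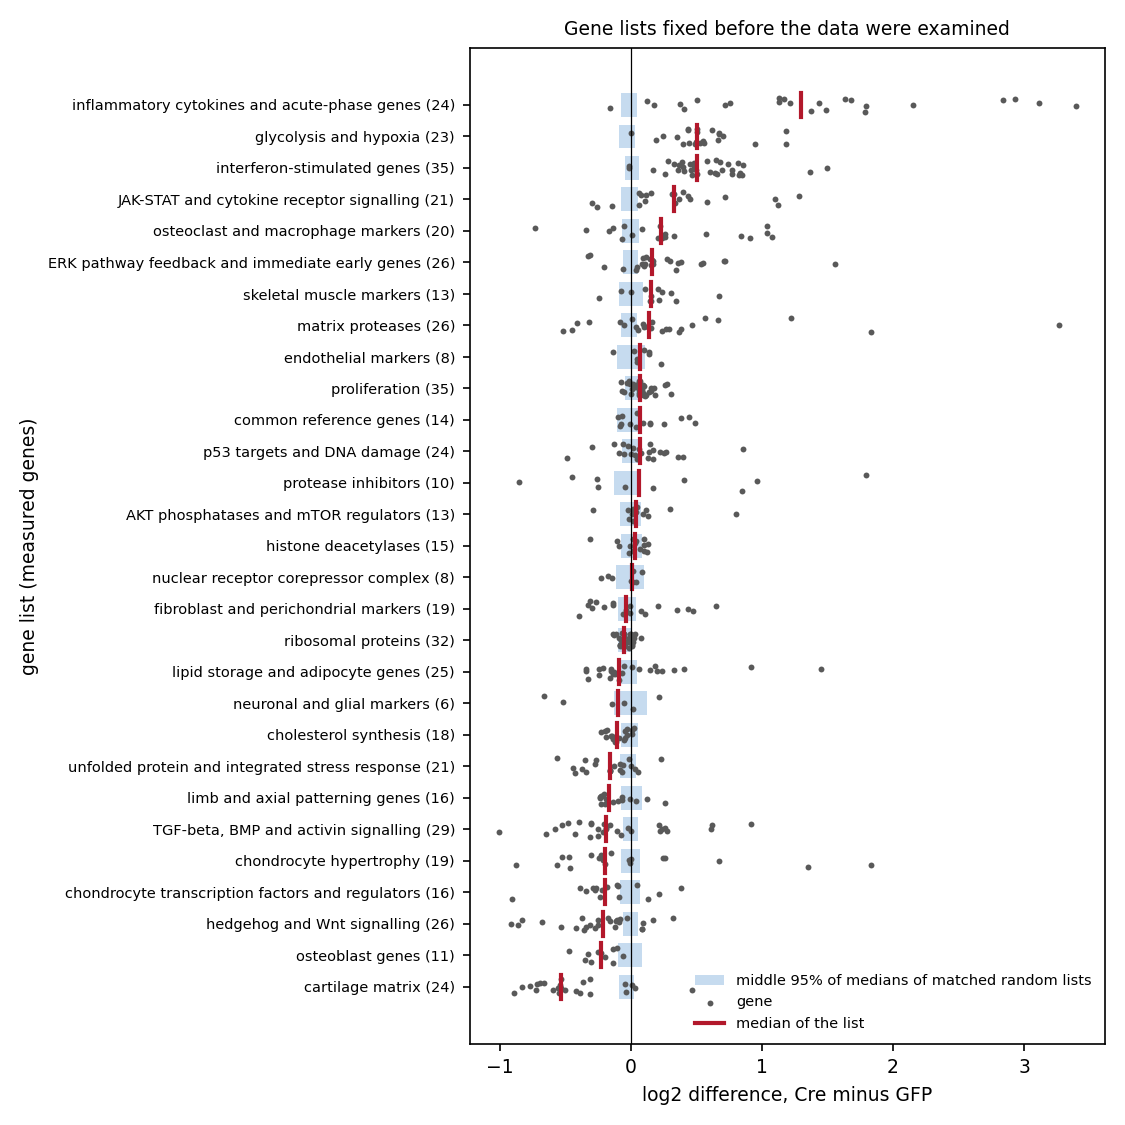
Each row is a gene list with at least 6 measured genes, the number in brackets, sorted by its median. The x axis is the log2 difference, Cre minus GFP. Points are genes, red bars are medians, and blue bands hold the middle 95% of the medians of 10000 random lists matched on expression. The inflammatory list lies highest, at 1.30, and the cartilage matrix list lowest, at -0.53.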

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

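Scaling to equal totals without Rn45s and Lars2 was chosen only after the data were seen, and all other alternatives before. The counts of 2-fold genes depended mainly on the threshold. At 1.5-fold, 288 genes were higher and 122 lower in the library labelled Cre, and at 4-fold 15 were higher and 1 lower. The share of higher genes was above that of lower genes at each threshold. Without a minimum, at a minimum 10 times higher and under the scalings tried, 79 to 94 genes were higher and 7 to 9 lower. Of 1344 genes with a mean log2 value from 5.64 to 7, 0 reached 2-fold. Removing the minimum, which adds genes of still lower abundance, could therefore hardly change these counts. The scalings moved every gene alike, with offsets of -0.00041 (median scaling), -0.0077 (equal totals) and -0.015 (equal totals without Rn45s and Lars2). They cannot move a percentile and barely move a median, so they are left out of the counts that follow, as are minimums that left the members of a list as they were. Of 59 other alternative values for list medians, 50 stayed within 0.1 of the main one. The mean in place of the median turned the hypertrophy list to 0.0072 and the lipid storage list to 0.049, since a few strongly higher members outweighed many slightly lower ones, and raised the matrix protease list to 0.33. At the minimum 10 times higher, the inflammatory list moved to 1.46 over 20 genes and the interferon list to 0.65 over 22, while the protease inhibitors turned from 0.06 to -0.046 (0.23 by the mean). The muscle markers moved there from 0.15 to 0.67 and the neuronal and glial markers from -0.10 to -0.59, with 1 and 2 genes left. Of 90 alternative percentiles, 80 stayed on the same side of the middle 95%, 8 moved into it and 2, both of the neuronal and glial list, out of it. Those that moved in belonged to the hypertrophy, proliferation, p53, lipid storage, cholesterol synthesis and common reference lists. Pseudocounts, TMM factors, thresholds on adjusted p-values and replicated tests were not run, since the table used here holds log2 values of 1 library per group. No paired analysis was possible because each group holds 1 library. With no counts, what depth limits cannot be told.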

Other observations

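The tests of the macrophage share, the scaling offset, the vectors, the chondrocyte share, the cell cycle and the reads shared by Aspm, Egln1 and Tmem158 were chosen only after the results they bear on were seen, as were the complement, metal handling and proteoglycan groups, the comparison of neighbouring genes, the test of imprinted genes far from those already seen, and the genes named among these and among the imprinted genes.

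Of 8 complement genes, all lay above 0 and 4 were at least 2-fold higher in the library labelled Cre: Cfb by 2.33, C3 by 1.79, Serping1 by 1.30 and C1s by 1.27 on the log2 scale. Of 13 genes of metal handling, 12 lay above 0 and 9 were at least 2-fold higher, among them Steap4 at 2.43, the metallothioneins Mt2 and Mt1 at 2.10 and 1.59, the haem carrier gene Hpx at 1.87, the zinc importer gene Slc39a8 at 1.57 and the ferritin heavy chain gene Fth1 at 1.29. The iron exporter gene Slc40a1 lay at -0.29. Of 11 small leucine-rich proteoglycan genes, 5 lay above 0, with a median of -0.18. Ogn, Aspn and Ecm2, neighbours of Omd on chromosome 13, lay at -1.08, -0.93 and -0.70, and Fmod on chromosome 1 at -0.50. Lum and Dcn on chromosome 10 lay at 0.65 and 0.47, and Prelp on chromosome 1 at 0.44.

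Genes higher in the library labelled Cre were neighbours more often than in shuffled data. Among 8041 pairs of adjacent measured genes with midpoints within 100 kb, 16 pairs were both at least 1.5-fold higher in the library labelled Cre, against a mean of 4.11 and a highest value of 10 in 1000 shuffles of the differences among genes of like abundance. Both members were lower in 5 pairs, against a mean of 0.77, and the highest shuffled value was also 5. Most of the higher pairs are members of 1 family (such as Ccl2 and Ccl7, Cxcl9 and Cxcl10, Gbp3 and Gbp2, Mt2 and Mt1). The excess therefore does not show an effect of position apart from family. Similar copies can share reads, which was not tested for these genes.

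The higher level of inflammatory genes in the library labelled Cre, with a median of 1.30, has more than 1 possible explanation. A larger share of macrophages would raise their own transcripts by at least as much, yet all 20 measured macrophage and osteoclast markers lay below 1.30, from -0.73 (Mrc1) to 1.08 (Emr1) with a median of 0.23, which argues against it as the whole cause and leaves a part, or another state of these cells, open. The list lay at percentile 100 of matched random lists, which 1 offset for all genes cannot bring about. Whether the Cre and GFP vectors or their transduction differed cannot be told apart from loss of Hdac3, because each vector is in 1 library only, and the interferon-stimulated genes, which a response to a vector could raise, had a median of 0.50. Loss of Hdac3, which the design names, also stays open and untested, since Hdac3 totals were level and no replicate exists.

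The cartilage matrix list was lower, with a median of -0.53. A trend across the bins of abundance does not account for this, since the list's percentile among random lists of like abundance was 0. The highest bin spans a wide range of abundance, so a trend among the most abundant genes was not excluded. A lower share of chondrocytes may contribute, which would raise the markers of whichever cell types took up the share, and not necessarily of all. Macrophage and osteoclast markers (median 0.23), skeletal muscle markers (0.15) and endothelial markers (0.07) lay above 0, while fibroblast and perichondrial markers (-0.033, quartiles -0.24 and 0.16) and neuronal and glial markers (-0.10) lay below. All 11 measured osteoblast genes also lay below 0 (median -0.23), some of them shared with the hypertrophy list. The neuronal and glial list lay apart from the muscle and endothelial lists by its quartiles. Only 6 of its genes were measured, among them S100b, which chondrocytes also express. Since not every list need rise, the values neither show nor exclude a lower share of chondrocytes. An effect of Hdac3 loss or of the inflammatory state of the culture on the cartilage matrix genes stays open.

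Some genes outside the lists were examined singly: Aspm at 2.60, and Tmem158, Akt1s1 and Egln1 at -2.04, -1.85 and -1.17. A difference in the cell cycle does not account for Aspm, since the highest of 35 proliferation genes lay at 0.31. Reads shared with other annotated genes do not account for Aspm, Egln1 or Tmem158, which share 0% of their stretches of 50 bases with another gene's annotated transcripts. Akt1s1 shares 1.93% with its overlapping neighbours Tbc1d17 and Mir707, and Tbc1d17 differed by -0.02, which goes against reads of Tbc1d17, while Mir707 was not analysed here and stays open. Reads from the vectors, unannotated copies in the genome and differences between single cultures were not tested.

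A hypothesis from the list of lower genes was that imprinted genes, which are expressed from 1 parental allele and often act on fetal growth, were lower as a group in the library labelled Cre. It arose from 7 genes whose values had been seen, among them Zim1 at -0.97, Peg10 at -0.94, Cdkn1c at -0.79 and Peg3 at -0.73. It was tested on 26 other measured imprinted genes listed before their values were looked at, some of them in the same imprinted clusters as the 7. Of the 26, 22 lay below 0, with a median of -0.21 and percentile 0 among 10000 matched random lists, whose middle 95% ran from -0.07 to 0.05. The lowest of the 26 were Plagl1 at -0.58, Rian at -0.41, Meg3 at -0.38 and Grb10 at -0.33, of which Rian and Meg3 lie near Dlk1, a gene of the 7. The 18 of the 26 that start over 2 Mb from each of the 7 had a smaller median of -0.10, at percentile 0.6, with 14 below 0. The differences are small and rest on 1 library per group, and imprinted genes may vary together between any pair of cultures, so replicates would be needed to tie this to Hdac3.

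Lars2 was second in abundance only to Rn45s, with 5.42% and 5.18% of the summed linear values in the libraries labelled Cre and GFP. The gene encodes a mitochondrial aminoacyl-tRNA synthetase, but its total does not show that these reads come from that messenger RNA. It was set aside with Rn45s as possible ribosomal signal in the scaling without both, and the origin of its reads was not tested.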
